A study of Bos taurus and Bos indicus with 6 samples.

How the data were processed

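Total RNA was extracted from the white blood cells of 6 female cattle, each 6 months old, during repeated heavy exposure to the cattle tick Rhipicephalus microplus. Per the labels, blood was drawn from the jugular vein, red cells were lysed, and the remaining pellet was taken as the whole white cell population with no sorting or culture. RNA from each animal was biotin-labelled and hybridised to its own bovine expression array, an Affymetrix GeneChip on which several short probes make up a probe set for a transcript. The labels name 3 Holstein and 3 Brahman animals, and the breeds are annotated as Bos taurus and Bos indicus. The replicates are therefore different animals, and the spread between them holds both animal and array variation.

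The deposited table holds 1 log2 expression value per probe set and array, made by the authors with RMA per the submitters' processing notes, and the version of RMA is not given in the sources used here. RMA corrects background, quantile-normalises the arrays together and summarises the probes of a probe set, so values are comparable between arrays, and a global change in RNA content would be removed. The table has 24128 probe sets, of which 112 are array controls and 24016 were tested. Values ran from 2.89 to 14.45. No scanner intensities and no detection calls were used here, so signal against background could only be judged from the level itself. The number of arrays, 3 per breed, limits the precision.

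Gene names came from the platform annotation table for these probe sets. That table gave 1 gene symbol for 13292 tested probe sets, several for 86 and none for 10638. The named probe sets cover 9155 genes. Of the 13292 probe sets, 13263 had an entry in the RefSeq gene table of the ARS-UCD2.0 assembly through their Entrez identifier, and 0 symbols differed. No genome build is named for the array, so no coordinates are given.

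Brahman was compared with Holstein on the log2 scale with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with its default prior), with breed as the only term. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over the 24016 probe sets, and a probe set was called at an adjusted p under 0.05. Differences are Brahman minus Holstein throughout, so a negative value is lower in Brahman. SE is the moderated standard error of that difference.

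Before the data were examined, 30 gene lists were written: markers of blood cell types, immune pathways, and general cell processes. Each was tested with limma's camera, which asks whether the genes of a list shift together in a common direction relative to the other genes. A list whose members differ in both directions need not be called. It used 1 probe set per gene, the brightest over all arrays, and a preset correlation of 0.01 between genes. The 29 lists with at least 5 measured genes were tested and adjusted together. The same lists were tested with the correlation estimated from the data and with fry. Fry has a directional test and a mixed test that ignores direction, and its list calls are those of the directional test. Counts of list members are given at an unadjusted p under 0.05, adjusted over the list alone, and adjusted over all probe sets. Array similarity was tested as the mean Pearson correlation of array pairs within a breed minus that between breeds, with an exact permutation test over the 10 splits of 6 arrays into 3 and 3. That test cannot give a p below 0.1.

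The rule for named genes was fixed at the same point. It takes up to 12 called probe sets in each direction with 1 gene symbol and no overlap between the breeds, then 3 members of each called list and 1 of every other list by smallest p. It adds any list member called over all probe sets where a list has 5 or fewer. Genes outside the rule are said to be chosen after their values were seen.

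The pipeline was tested on simulated data of 24016 probe sets, with variances drawn from the prior that limma fitted to the real data. The noise was normal and independent between probe sets, as limma assumes, without any array or spike-in effect. In 10 runs the pipeline called 79.6% of probe sets changed by 1 log2 unit and 97.5% of those changed by 2, and 6.15% of its calls were false. These rates may not hold for the real arrays, which need not meet those conditions. For a simulated list of 79 genes without any shift, camera with the preset correlation called 1% of 100 runs when genes were independent and 57% when their correlation was 0.24. With the correlation estimated it called 7% of the latter. With a shift of -0.33 and that correlation, the preset setting called 100% and the estimated setting 90%. These list rates count an unadjusted p under 0.05 for 1 list tested alone, unlike the real list calls, which were adjusted over 29 lists.

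Alternatives fixed in advance were another normalisation, filters on dim probe sets, another prior, array weights, the replicate number as a block, 1 value per gene, a size threshold, other list tests, and each array left out in turn. Samples of the 2 breeds share replicate numbers in their titles, but these name different animals, so the numbers were not used as pairs. The level of the hybridisation spike-in controls as a covariate was added after seeing the data, as were the counts of list members without each array.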

Results

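Gene expression was measured in circulating white blood cells of 3 Brahman and 3 Holstein cattle, all under heavy infestation with the tick Rhipicephalus microplus. Brahman are zebu cattle, generally regarded as more resistant to this blood-feeding tick than European breeds such as the Holstein. The comparison asks which transcripts of circulating leukocytes differ between the breeds when both carry ticks. Arrays of uninfested animals were not analysed here, so differences that exist without ticks are included in every value. The median log2 value of an array lay between 6.54 and 6.61.

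On average, arrays of a breed correlated slightly better with each other than with arrays of the other breed, but this did not hold for Holstein 3. The mean correlation over probe sets was 0.987 within Holstein, 0.990 within Brahman and 0.985 between breeds. Within-breed pairs exceeded between-breed pairs by 0.0041 on average, with a one-sided exact permutation p of 0.1, the smallest that 3 against 3 arrays allow, and p was 0.2 without Brahman 1 or Brahman 3. The first principal component held 37.4% of the variance and placed the Brahman arrays at 19.66, 19.84 and 20.01, against -22.87, -30.51 and -6.12 for Holstein. Holstein 3 was the Holstein array nearest to the Brahman arrays, and correlated with Brahman 1, 2 and 3 at 0.988, 0.989 and 0.987, against 0.987 and 0.988 with Holstein 1 and 2.

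**Figure D1:**
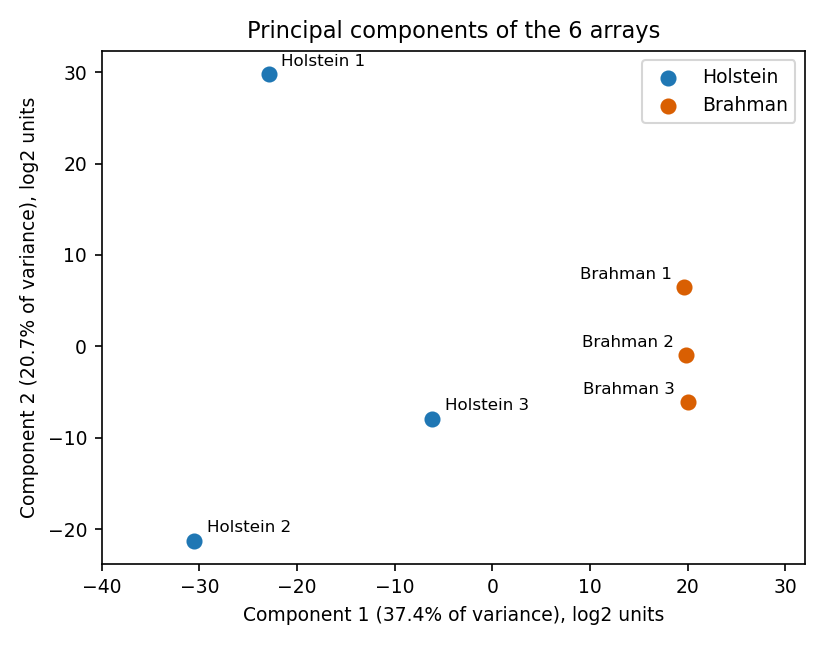
Positions of the 6 arrays on the first and second principal components of all tested probe sets, in log2 units, coloured by breed. The Brahman arrays lie together near 20 on the first component, and the Holstein arrays spread from -30.51 to -6.12.

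In the main fit, leukocytes of Brahman cattle gave more signal for a probe set each of granzyme B and SLAMF6. Granzyme B is a cytotoxic granule protease and SLAMF6 a receptor on NK and T cells. Brahman leukocytes gave far less signal for a probe set each of the transcription factor FOXP1, the phosphatase inhibitor PPP1R1B and PTGR1. PTGR1 is an enzyme that inactivates leukotriene B4. GZMB averaged 9.70 ± 0.25 in Brahman and 7.19 ± 0.54 in Holstein (log2, SD, n = 3 each), a 5.70-fold difference. With each array left out in turn, GZMB stayed called in 2 of 6 fits and SLAMF6 in 1. Neither was called with the spike-in level as a covariate. PPP1R1B averaged 5.88 ± 0.28 in Brahman and 8.99 ± 0.16 in Holstein, 8.64-fold higher in Holstein. In all, limma called 33 of 24016 probe sets, 19 higher and 14 lower in Brahman, and 17 of them carried a single gene symbol, for 16 genes.

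Among the genes higher in Brahman, GZMB differed by 2.51 (SE 0.26, adjusted p = 0.0264) and SLAMF6 by 2.08 (SE 0.25, adjusted p = 0.0416). ATP4B, which encodes the beta subunit of the gastric proton pump, was higher by 1.73 (SE 0.17, adjusted p = 0.0207). The calcium-dependent phospholipid-binding protein gene CPNE8 was higher by 1.46 (SE 0.12, adjusted p = 0.0126), from a Holstein mean of 3.88 that is likewise not shown to be above background, so its size is uncertain. SPATS2L was higher by 1.18, the corepressor gene TLE1 by 1.08 and RHOT1, a GTPase of the outer mitochondrial membrane, by 1.04, with adjusted p-values of 0.0258, 0.0416 and 0.0451. TLE1 has other probe sets, which differed by 0.59 and 0.06 and were not called.

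Among the genes lower in Brahman, the called FOXP1 probe set differed by -3.29 (SE 0.13, adjusted p = 0.000541) and stood at 3.73 ± 0.21 in Brahman against 7.02 ± 0.14 in Holstein. The Brahman level lies below the lower quartile of all probe sets (5.08) and is not shown to be above background, so the size of this difference is uncertain. A second FOXP1 probe set was called in the opposite direction, higher in Brahman by 2.18 (adjusted p = 0.0171), so the array gives no single direction for this gene. PPP1R1B differed by -3.11 (adjusted p = 0.00136), PTGR1 by -3.03 (adjusted p = 0.0156) and NEB, the gene of the muscle thin filament protein nebulin, by -2.17 (adjusted p = 0.0364). The other PTGR1 probe set was lower by the same sign, at -1.23, with an adjusted p of 0.0719. The oxidised lipoprotein receptor OLR1 (-1.34), the actin regulator CYFIP1 (-1.09), TMEM127 (-1.41), the centromere protein CENPS (-1.01) and GAS7 (-0.84) were called lower with adjusted p-values from 0.0258 to 0.0416. Other probe sets of TMEM127 differed by -0.15, -0.17 and 0.07. Those of NEB (0.16 and 0.06) and CYFIP1 (-0.03) averaged 4.26, 3.90 and 4.94, levels not shown to be above background, so they may be unable to show a decrease. In Holstein they read 4.18, 3.87 and 4.96, where the called probe sets of NEB and CYFIP1 read 8.76 and 9.80. The probe sets of these genes therefore disagree on level as well, and which of them measures the gene was not tested.

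**Figure D2:**
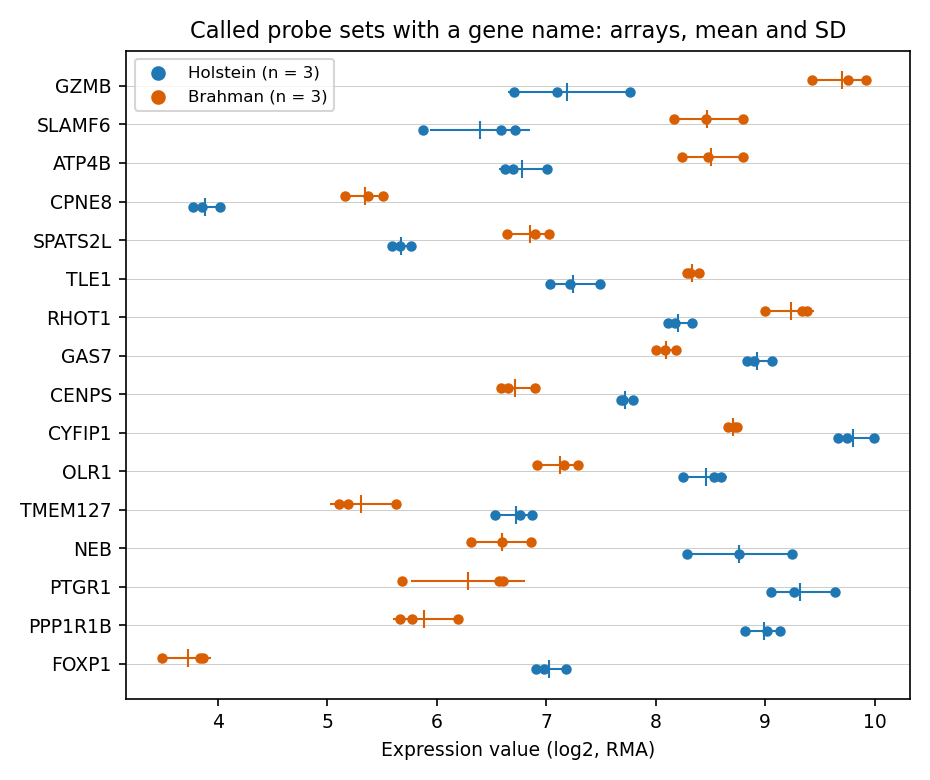
Log2 values of the called probe sets with a gene name, with a point per array and the mean and SD of each breed (n = 3). No overlap between the breeds was a condition for these 16 genes to be drawn. The FOXP1 gap rests on a Brahman mean of 3.73, not shown to be above background. The other called FOXP1 probe set (2.18) is not drawn.

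The remaining 16 called probe sets had no single gene name in the annotation used here. The 2 largest differences in each direction among them were 4.03 and 2.47, higher in Brahman, and -2.38 and -1.35, with adjusted p-values of 0.0364, 0.00608, 0.00892 and 0.0139. The first of these has a Holstein mean of 4.69, below the lower quartile of all probe sets (5.08) and not shown to be above background, so its size and rank are uncertain. Beyond the calls, 3263 probe sets had an unadjusted p under 0.05, where chance gives 1201 on average. In 4811 (20.0%) the breeds did not overlap, where chance gives 10% on average. The first count ran from 2315 without Brahman 3 to 3842 without Holstein 3. Neither count was made for other splits of the arrays, so the excess is not shown to belong to breed. The count of calls depended on single arrays: it was 18, 8 and 55 without Holstein 1, 2 and 3, and 11, 5 and 21 without Brahman 1, 2 and 3. Of the 16 named genes, FOXP1 and PPP1R1B were called in each of these 6 fits, PTGR1 and CPNE8 in 4, CENPS and GAS7 in 0 and the others in 1 to 3, and with the spike-in level as a covariate limma called 0 probe sets, with 2400 at an unadjusted p under 0.05.

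The list of genes for the mitochondrial respiratory chain, the complexes that make ATP from oxygen, was called lower in Brahman. Of 79 measured genes 75 had lower values, with a median difference of -0.33, and 50 reached an unadjusted p under 0.05, all of them lower. The per-array mean of the list was 10.07 ± 0.05 in Brahman and 10.37 ± 0.09 in Holstein, with no overlap. The smallest p-values were those of the complex I subunits NDUFC2 (-0.57, SE 0.10), NDUFC1 (-0.61, SE 0.11) and NDUFA3 (-0.46, SE 0.09). Camera gave an adjusted p of 2.56e-19, and 0.672 with an estimated correlation between genes, which was 0.24 for this list. At that correlation the preset setting gave an unadjusted p under 0.05 in 57% of simulated lists without any shift. How often such lists reach a p as small as the observed one (8.84e-21 in camera, unadjusted) was not computed. Adjusted over the list alone 42 genes passed, against 0 over all probe sets, and these became 6, 0 and 40 without Holstein 1, 2 and 3 and 0 without any of the Brahman arrays.

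The list for the proteasome, which degrades tagged proteins, was called lower as well: 29 of 32 had lower values, with a median of -0.20 and a camera adjusted p of 8.00e-05, or adjusted p = 0.672 with an estimated correlation. Among them PSMC2 differed by -0.49, the immunoproteasome subunit PSMB10 by -0.55 and PSMC1 by -0.30. Of the members, 8 reached an unadjusted p under 0.05 and 0 passed adjusted over the list alone. The former count was 3, 3 and 15 without Holstein 1, 2 and 3, and 8, 3 and 2 without Brahman 1, 2 and 3. Ribosomal protein genes had a median of 0.01 over 61 genes with no list call, and RPS9 (0.26) had the smallest p of that list. At a median level of 13.66, near the highest of any gene (14.38), a difference in them might not be seen.

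The list of T cell markers was called higher in Brahman. Of 22 markers 18 had higher values, with a median of 0.33, and 14 reached an unadjusted p under 0.05, all higher. The CD40 ligand gene CD40LG differed by 0.74 (SE 0.14), LEF1, a transcription factor of naive T cells, by 0.96 (SE 0.18), and the T cell receptor subunit gene CD3E by 0.54 (SE 0.11). Camera gave an adjusted p of 9.96e-09, and 0.353 with an estimated correlation. Adjusted over the list alone 10 genes passed, 6 without Brahman 1, against 0 over all probe sets.

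Genes of type 1 helper and T cell activation were also called higher, with a median of 0.14 over 19 genes, 13 of them higher, and a camera adjusted p of 0.0103 (adjusted p = 0.672 with an estimated correlation). The interleukin 2 receptor chain gene IL2RA (1.03) and STAT4 (0.66), a signal transducer for interleukin 12, passed adjusted over the list alone, and CD44 differed by 0.43 without passing. The 6 lower members include the interferon gamma gene IFNG (-0.23) and the interleukin 12 receptor gene IL12RB2 (-0.01), neither passing and both chosen after their values were seen. The list call was lost without Holstein 2, Holstein 3 or Brahman 1, with camera adjusted p-values of 0.0532, 0.0559 and 0.0623. The median was 0.07 without Holstein 3 and 0.09 without Brahman 1, where 1 gene passed adjusted over the list alone. The list of NK and cytotoxic lymphocyte genes, which holds GZMB, was not called (22 genes, 14 of them higher, median 0.09, adjusted p = 0.343), and its median ran from -0.02 without Brahman 1 to 0.12 without Brahman 2. After GZMB, the members with the smallest p-values went in both directions and did not pass adjusted over the list alone: the receptor gene KLRD1 at 0.90 and perforin (PRF1) at -0.60, both chosen after their values were seen.

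Of 35 genes induced by interferon 33 had lower values in Brahman, 5 of them at an unadjusted p under 0.05, with a median of -0.39 and a camera adjusted p of 0.00111, or adjusted p = 0.720 with an estimated correlation. IFI35 (-0.84, SE 0.17) was the only gene lower adjusted over the list alone, while GBP4 (-1.24, SE 0.34) and IFIT2, which went the other way (0.96, SE 0.25), did not. The animals of the Brahman group differed widely: the mean of the list was 9.48, 8.78 and 8.51 on Brahman 1, 2 and 3, and 9.31 ± 0.20 in Holstein. Without Brahman 1 the median was -0.55 and 16 genes were lower adjusted over the list alone, without Brahman 3 it was -0.11 with an adjusted p of 0.131, and without Holstein 2 it was -0.24. The count of genes lower adjusted over the list alone was 3 without Holstein 3 and 0 without Holstein 1, Holstein 2, Brahman 2 or Brahman 3. At an unadjusted p under 0.05 the count of lower genes was 10 without Holstein 3, 20 without Brahman 1, 3 without Brahman 3 and 5 without each other array.

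In the list of Toll-like receptor and pattern recognition signalling 18 of 23 genes had lower values in Brahman (median -0.15, camera adjusted p = 0.0287, adjusted p = 0.672 with an estimated correlation). CARD9 (-0.57) and PYCARD (-0.72), adaptors of fungal and inflammasome sensing, and the kinase IRAK4 (-0.68) passed adjusted over the list alone. In the list of oxidative and antioxidant defence 27 of 34 genes had lower values (median -0.13, camera adjusted p = 0.0216, adjusted p = 0.672 with an estimated correlation). NCF4 (-0.70, SE 0.10), a subunit of the phagocyte oxidase, passed adjusted over the list, and the antioxidant regulator NFE2L2 (-0.57) and PRDX2 (-0.79) did not. The Toll-like call was lost without Holstein 1, Holstein 3, Brahman 1 or Brahman 2 (adjusted p = 0.104, 0.0559, 0.0623 and 0.0720), and the 3 genes became 0, 1, 1, 0, 3 and 0 without Holstein 1, 2 and 3 and Brahman 1, 2 and 3. The oxidative call was lost without Holstein 1 (adjusted p = 0.0876) or Brahman 1 (0.0623), and its 1 gene became 3 without Holstein 3 and 2 without Brahman 3.

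Of 40 cell proliferation genes 31 had lower values in Brahman, with a median of -0.19 and a camera adjusted p of 0.00206, or adjusted p = 0.720 with an estimated correlation. The cyclins CCNB2 (-0.80) and CCNA2 (-0.55) and the spindle protein NUSAP1 (-0.84) had the smallest p-values, and 0 members passed adjusted over the list alone, with 8 lower and 1 higher at an unadjusted p under 0.05. The median was -0.29 without Brahman 1 and -0.11 without Brahman 3, and without Brahman 2 the adjusted p was 0.0532. The 8 lower genes became 4 without Holstein 2 and 15, 5 and 4 without Brahman 1, 2 and 3, and 3 genes without Holstein 3 and 5 without Brahman 1 passed adjusted over the list alone.

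**Figure D3:**
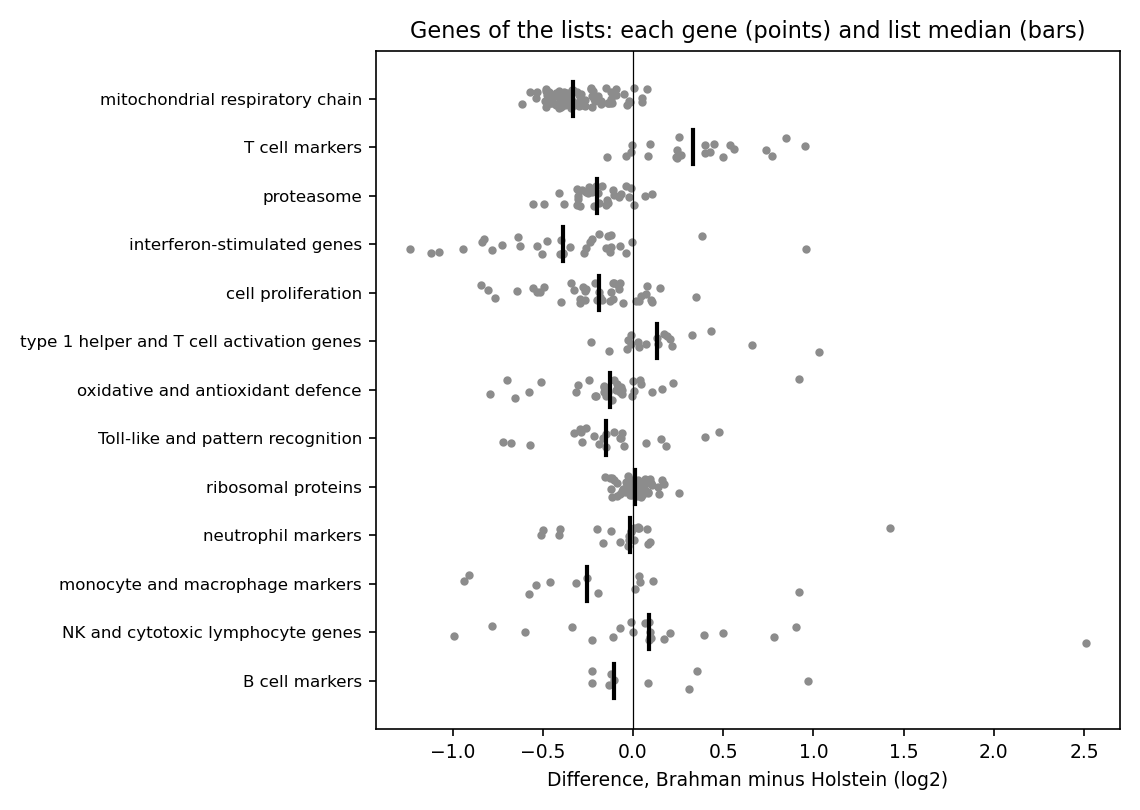
Differences between the breeds (log2, Brahman minus Holstein) of the genes in the 8 called lists and 5 lists that were not called, with a point per gene and a bar at the median. Respiratory chain genes lie almost all below 0 and T cell markers mostly above it, while ribosomal protein genes centre on 0.01.

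None of the 8 list calls, 2 higher and 6 lower in Brahman, held with an estimated correlation between genes or in fry's directional test. The estimated correlation ran from 0.04 (Toll-like) to 0.55 (interferon) over these lists, above the preset 0.01. The directional fry adjusted p was 0.0611 for T cell markers, 0.0828 for the respiratory chain and 0.235 to 0.559 for the other called lists. Fry's mixed test ignores direction. Its adjusted p was under 0.05 for the T cell, type 1, respiratory chain, Toll-like and oxidative lists, but not for the other called lists. It was also under 0.05 for lists that camera did not call, such as the NK and adhesion lists (0.00452 each). The hybridisation spike-in controls were higher on every Holstein array than on any Brahman array, at 10.14 ± 0.22 against 9.72 ± 0.08, and the actin 3′ to 5′ difference was 1.86 ± 0.13 against 1.69 ± 0.04. The same difference was also larger in Holstein for GAPDH, cyclophilin and eIF-4E, by 0.147, 0.134 and 0.141, with overlap between the breeds (exact permutation p = 0.3, 0.4 and 0.2). The mean levels of the respiratory chain, T cell, proteasome and Toll-like lists separate the breeds without overlap, as the spike-in and actin controls do. The proteasome gap is very narrow, at 9.969 on Holstein 3 against 9.965 on Brahman 1. That of actin is as well, at 1.728 on Holstein 1 against 1.722 on Brahman 3. The mean levels of the interferon, proliferation, type 1 and oxidative lists do not separate the breeds. With the spike-in level as a covariate, the camera adjusted p at the preset correlation was 2.95e-07 for the respiratory chain, 4.15e-05 for T cell markers, 0.0142 for the proteasome and 0.0347 for interferon-stimulated genes. No value at an estimated correlation is given for this covariate, so these p-values carry the same limit as the main list calls. Proliferation (median -0.14, adjusted p = 0.117), oxidative defence (-0.12, 0.127) and Toll-like signalling (-0.21, 0.0689) were no longer called although their medians kept most of their size or grew, and type 1 and T cell activation had a median of -0.03 (0.945). Lists for MHC class I presentation (-0.58, adjusted p = 0.00019) and immediate early genes (-0.26, 0.0136) were called lower with this covariate and not without it.

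**Figure D4:**
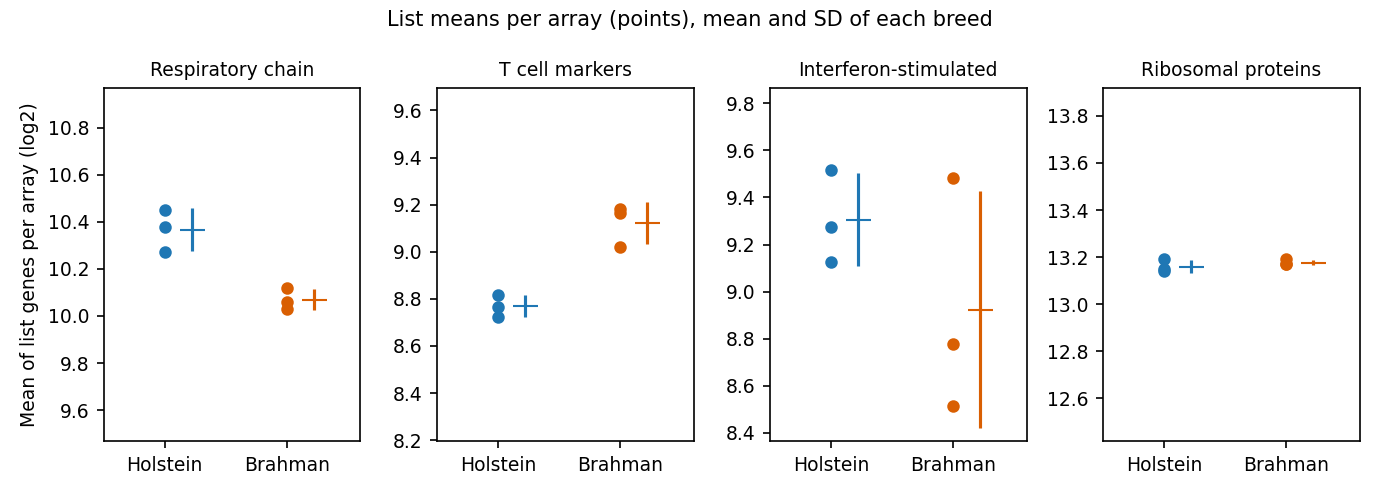
Mean log2 value per array of 4 gene lists, with a point per array and the mean and SD of each breed (n = 3). The breeds do not overlap for the respiratory chain and T cell markers, whereas Brahman 1 lies among the Holstein arrays for interferon-stimulated genes and ribosomal protein genes differ by 0.01.

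Markers of other blood cell types gave no list call. Neutrophil markers, the most abundant granulocyte class, had a median of -0.02 over 22 genes, although ALPL (1.42, SE 0.22) passed adjusted over the list alone. Monocyte and macrophage markers had a median of -0.25 over 13 genes, with members in both directions: the matrix proteoglycan gene VCAN was higher by 0.92 and CD14, chosen after its value was seen, differed by -0.94. Without Holstein 3 the count of lower genes adjusted over the list alone was 3 in place of 1. In the B cell list the kinase gene BLK was higher by 0.97, 1 of 2 genes to pass adjusted over the list alone (1 with any single array left out), and the 9 genes had a median of -0.11, a mean of 0.10 and a test direction of higher. Gamma delta T cell markers had a median of 0.16 over 6 genes, 5 of them higher, with an adjusted p of 0.0946 and ID3 higher by 0.54. Plasma cell genes (7 genes, FKBP11 0.20), dendritic cell markers (9 genes, CD86 -0.66), basophil and mast cell markers (6 genes, SLC18A2 0.43), platelet markers (11 genes, F13A1 -0.43) and red cell precursor markers (14 genes, ALAS2 -0.56) had medians of -0.02, -0.09, 0.12, 0.04 and 0.01. Median, mean and test direction did not share a sign for plasma cell, platelet and red cell precursor genes either. With 1 array left out the medians ran from -0.10 (without Holstein 3) to 0.03 (Holstein 1) for neutrophil, from -0.33 (Holstein 3 or Brahman 2) to -0.14 (Holstein 1) for monocyte, from -0.11 (Brahman 2) to 0.02 (Holstein 2) for B cell and from 0.07 (Holstein 2) to 0.25 (Brahman 1) for gamma delta T cell markers. They ran from -0.11 (Brahman 1) to 0.05 (Holstein 3) for plasma cell, from -0.26 (Holstein 3) to 0.01 (Holstein 1) for dendritic cell, from 0.07 (Holstein 2) to 0.16 (Holstein 3) for basophil and mast cell, from -0.03 (Brahman 2) to 0.10 (Holstein 3) for platelet and from -0.06 (Holstein 3) to 0.04 (Holstein 1) for red cell precursor genes. Of eosinophil markers 4 genes were measured, too few for the list test, with differences from -0.29 (SMPD3) to 0.07 (CCR3).

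Other immune and stress lists were not called. MHC class I presentation had a median of -0.15 over 18 genes (adjusted p = 0.0946), with PSMB10 at -0.55. Its median was -0.01, -0.23 and -0.25 without Holstein 1, 2 and 3 and -0.24 without Brahman 3, and the list was called without Holstein 2 (adjusted p = 0.0144). MHC class II presentation had a median of -0.11 over 15 genes, with BOLA-DMB at -0.28. Calcium signalling had a median of 0.10 over 34 genes (adjusted p = 0.0946). Its members ATP2B1, a plasma membrane calcium pump (-1.28), and the phospholipase gene PLCG1 (0.72), chosen after its value was seen, passed adjusted over the list alone in opposite directions, and 0 did so without Holstein 2, Brahman 1 or Brahman 3. Without Holstein 1 and Brahman 2 the counts were 0 and 1 higher and 1 and 0 lower, and without Holstein 3 they were 1 and 2. The other ATP2B1 probe sets differed by -0.03 and 0.06. Leukocyte adhesion and migration had a median of 0.09 over 30 genes, with the galectin gene LGALS3 higher by 0.46. It was the only gene to pass adjusted over the list alone, and the count was 4 without Holstein 1 and 0 without Holstein 2 or any Brahman array. Complement and Fc receptors had a median of -0.04 over 26 genes, with clusterin (CLU) lower at -1.35, the only gene to pass adjusted over the list alone, where 4 were lower without Holstein 3. Inflammatory cytokines (30 genes, IL15 -0.88), the NF-kappa-B pathway (17 genes, CFLAR 0.28), type 2 and regulatory cytokine genes (21 genes, CCR4 1.04), immediate early genes (23 genes, MYC 0.53) and heat shock and unfolded protein response genes (25 genes, EIF2AK3 0.37) had medians of -0.02, -0.13, 0.03, 0.08 and -0.10, and 0 of their members passed adjusted over the list alone. That count depended on single arrays. Without Holstein 3 it was 3 lower for inflammatory cytokines, and 1 higher and 3 lower for heat shock genes. Without Brahman 3 it was 1 higher and 1 lower for inflammatory cytokines, and without Brahman 1 it was 1 higher for type 2 genes. With 1 array left out the immediate early median ran from -0.06 (without Holstein 2) and -0.03 (Brahman 2) to 0.18 (Holstein 1), where the list was called higher with an adjusted p of 0.026. The others ran from -0.23 (Holstein 3) to 0.08 (Holstein 1) for NF-kappa-B, from -0.13 (Holstein 3) to 0.002 (Brahman 2) for inflammatory cytokines, from -0.002 (Brahman 1) to 0.15 (Holstein 1) for type 2 genes and from -0.17 (Holstein 3) to -0.01 (Holstein 1) for heat shock genes. For complement they ran from -0.18 (Holstein 3) to 0.02 (Holstein 1), for MHC class II from -0.16 (Brahman 2) to -0.05 (Holstein 1) and for adhesion from 0.05 (Holstein 3) to 0.08 (Brahman 1).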

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

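The tests of the spike-in effect, of short abundant messengers and of probe sequence differences, and the spike-in covariate, were chosen only after the results they bear on were seen.

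The hybridisation spike-in controls, added in fixed amounts to every sample and not part of the breed comparison, were brighter on Holstein arrays by 0.422 (10.14 ± 0.22 against 9.72 ± 0.08, SD, n = 3, exact permutation p = 0.1, the smallest possible), with all 3 Holstein arrays above all 3 Brahman arrays, whereas the labelling controls differed by 0.0033. Such a difference in hybridisation might also set the breed differences of other probe sets. The part of their variance that ran along the within-breed slope on the spike-in level was 25.1%, with a range from -35% to 85.2% (plus and minus 2 SD over random within-breed directions), so a hybridisation effect and breed cannot be told apart for the array as a whole because 6 arrays are too few. An earlier form of the test, a slope of 0.095 with a bound of 0.5, was replaced because noise in the slopes would hold even a full effect to 0.379. With the spike-in level as a covariate the 33 called probe sets kept their sign and a median of 95.3% of their size, while the median SE rose from 0.138 to 0.234, the median absolute difference went from 1.42 to 1.27 and the residual df from 4 to 3, and which of these ended the calls was not tested (breed and spike-in level were correlated at -0.84).

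Brahman cattle belong to another species than the animals most bovine sequence comes from, so sequence differences under the probes could lower the signal on Brahman arrays without any difference in transcript. Such a loss of signal on Brahman arrays would not give the 19 of 33 called probe sets that were higher in Brahman. Those 19 do not bear on the 14 lower calls. For the calls lower in Brahman, the other 8 probe sets of the same genes had a median difference of 0.015 (95% bootstrap interval -0.172 to 0.159), too few to decide. Of these, 3 (NEB at 4.26 and 3.90, CYFIP1 at 4.94) lie below the lower quartile of level, 5.08, and may be unable to show a decrease. The selection of these probe sets was changed after a first value was seen, and it includes the FOXP1 probe set that was higher in Brahman (2.18) and the PTGR1 probe set that was lower (-1.23). The real split of the arrays called 33 probe sets and the highest of the other splits 4, so 1 of the 10 splits, the real one, gave as many, too few splits for a share under 0.05, and a breed difference in transcript level stays open as untested.

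The lower values of respiratory chain genes in Brahman (median -0.33) were set against technical and cell mixture explanations. A trend that lowers all bright messengers is argued against, since 0% of 10000 random lists matched on level had a median as low, their medians running from -0.195 to 0.0466. A loss of short abundant messengers remains open: ribosomal protein genes had a median of 0.0112 (95% interval -0.0112 to 0.0273), but at a median level of 13.66, near the highest of 14.38, they may be saturated, and the test was set aside for this only after its value was seen. A larger share of T cells in Brahman blood also cannot be told apart from a change within cells, as the within-breed slope on the T cell marker mean predicts a difference of -0.0569 with a 95% interval from -0.7 to 0.586, which holds the observed -0.298, and the same slope on the spike-in level, tried and not kept, gives -0.0525 (-0.366 to 0.261). Over all lists the real split called 8 and the highest of the other splits, which mix the breeds, 10. Of the 10 splits 3, the real one included, were at 8 or more, and 10 splits could not give a share under 0.05. The number of list calls therefore does not set breed apart from other groupings of these arrays. Breed itself stays open as an untested biological explanation.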

How the results depend on the processing

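The spike-in covariate was chosen after seeing the data; the other alternatives were planned. The 33 calls (19 higher, 14 lower) became 33 (20 and 13) after another quantile normalisation, 30 (16 and 14) after median centring, 30 (15 and 15) and 37 (21 and 16) with probe sets at or above the median or the lower quartile of level, 42 (23 and 19) with a trended robust prior, 30 (17 and 13) with array weights and 28 (16 and 12) with a 2-fold minimum. They became 15 (8 and 7) with the brightest probe set per gene and 13 (7 and 6) with probe sets averaged, which test fewer values, and 0 (0 and 0) with the spike-in covariate. Leaving out each array gave 5 to 55 calls (3 to 25 higher, 2 to 30 lower), and all 33 kept their sign. FOXP1 reversed to 2.18 with the brightest probe set per gene, which is its other probe set. With the replicate number as a block limma called 10 (5 higher, 5 lower), all among the 33; deviations of same-numbered arrays correlated at 0.111, -0.0425 and -0.0737, not every array correlated best with its own number, and the numbers name different animals. The 8 list calls (2 higher, 6 lower) became 0 (0 and 0) with an estimated correlation and 0 (0 and 0) with fry, 6 (3 and 3) among brighter genes, 7 (3 and 4) after another quantile normalisation, 8 (2 and 6) with probe sets averaged or a variance trend, 9 (2 and 7) with the replicate block and 6 (1 and 5) with the spike-in covariate. With that covariate the medians of type 1 and T cell activation genes and of immediate early genes reversed to -0.0317 and -0.263, and the small medians of basophil and mast cell, adhesion and type 2 genes also changed sign, to -0.0192, -0.0145 and -0.0879; the cause was not tested. Leaving out each array gave 5 to 8 lists (1 to 3 higher, 4 to 7 lower). The within-breed minus between-breed array correlation was 0.0122 among brighter probe sets, 0.00433 by Spearman correlation and 0.00328 to 0.00631 without each array.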

Other observations

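The genes below were chosen after their values were seen, as those with the widest spread between animals of a breed. Probe sets of MHC class II genes of the DQ group, which present peptides to helper T cells, differed between animals far more than between breeds. A BOLA-DQA2 probe set read 5.12 on Holstein 1 and 5.03 on Brahman 3, and from 11.79 to 12.95 on the other 4 arrays. A BOLA-DQB1 probe set read 4.87 and 6.2 on the same arrays and from 11.88 to 13.45 on the others. A different BOLA-DQB1 probe set was its mirror image, at 12.29 on Holstein 1 and 12.03 on Brahman 3 and from 4.97 to 6.74 elsewhere, so these values give no level of the gene as a whole. BOLA-DQA5 went the other way on Brahman 3, at 9.87 against 5.2 to 5.84 elsewhere. The within-breed SD was 4.3 for the BOLA-DQA2 probe set and 4.25 for the first BOLA-DQB1 probe set, against a median of 0.147 over all probe sets, and their breed differences were -0.32 and 0.00 with limma adjusted p-values of 0.976 and 1.00.

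Single animals also stood apart for other genes. GSTO1, a glutathione transferase, read 4.85 on Holstein 3 and 8.26 or more on the other arrays. PRSS2, a trypsin gene, read 11.29 on Holstein 2 and from 5.08 to 6.35 elsewhere. A probe set of the MHC class I gene BOLA-N read 9.44 on Brahman 1 and 10.32 on Holstein 3, against 12.38 to 13.64 on the others.

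Among 2910 genes with several probe sets, the breed differences of the brightest pair correlated at 0.412 across genes, which are not independent replicates, and had the same sign in 63.9%.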
